A study of Mus musculus with 54 samples.

How the data were processed

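Messenger RNA was sequenced from mouse ESC, EpiLC and day 2 PGCLC of 9 lines, 2 libraries for each of 27 groups. Per the labels' protocols, RNA was isolated with the RNeasy Micro kit, mRNA was selected by poly(A), and libraries were made with the NEBNext Ultra Directional kit and 12 PCR cycles. The labels give the strain as C57BL/6 X 129/SvJ. Reads were aligned to mm10 with HISAT2, counted with featureCounts and processed further with edgeR, per the submitters' processing notes. Versions, the annotation and the strand setting are not given in the sources used here. The deposited values are TPM, per the labels, and every library sums to the same total, so they show shares of the mRNA and not amounts per cell.

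Groups were taken from the sample titles. In 8 libraries the cell type tag in the labels differs from the title: the PGCLC pair of Ovol2a-Tg is tagged EpiLC, the ESC pair of Cdh1-Tg is tagged PGCLC, and its EpiLC and PGCLC pairs are tagged ESC. For 2 columns, those of Ovol2b-Tg EpiLC, the names fix the group but not which library is which. No column of single samples was left out. The labels describe the lines in different naming styles, which might mark separate batches: a plain style for WT, the knockout-labelled lines and Ovol2b-Tg, and 3 further styles for Ovol2a-Tg, Ovol2a/2b-Tg and Cdh1-Tg. Such batches would be wholly confounded with the line. The background of the transgenic lines is not given in the sources used here, and TKO is not spelled out.

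Whole reads were recovered from the TPM values for 17973 of 20036 genes, those above 0. This gave 2.16 to 26.73 M reads per library (median 8.65 M). WT PGCLC had 5.22 and 6.94 M, those labelled Ovol1KO 2.37 and 5.6, Ovol2KO 10.31 and 2.64, Ovol3KO 17.25 and 2.58, and TKO 2.94 and 12.34. Among the transgenic PGCLC the reads were 26.73 and 23.55 M in Ovol2a-Tg, 21.9 and 2.46 in Ovol2b-Tg, 8.58 and 8.77 in Ovol2a/2b-Tg and 14.65 and 12.45 in Cdh1-Tg. Replicate pairs were checked for spread beyond read sampling. Chi-square per degree of freedom was 1.05 to 10.87 (median 2.41), and 0 of 27 pairs had a p at or above 0.05. The value of 1.05 belongs to the Ovol2b-Tg EpiLC pair, which varied hardly beyond read sampling and may be 1 sample sequenced as 2 libraries. The next lowest were 1.32 in Cdh1-Tg EpiLC, 1.37 in Ovol2a/2b-Tg ESC and 1.43 in Cdh1-Tg PGCLC. Those pairs also varied little beyond read sampling, so the same doubt holds for them, but only the Ovol2b-Tg pair was averaged as a check. On simulated WT PGCLC pairs the same measure gave 1 with sampling noise only and 3.84 with biological spread.

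Tests used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend and robust shrinkage. Genes needed a TPM of at least 1 in at least 2 libraries, which left 14416. Adding 1 to the TPM makes the fold changes of scarce genes smaller than their ratio. Lines were compared within a stage in a fit of the 18 libraries of that stage (9 residual degrees of freedom). WT stages and the difference of a line's effect between PGCLC and EpiLC were tested in a fit of all 54 libraries (27 residual degrees of freedom). A gene was called changed at a Benjamini-Hochberg (BH) adjusted p under 0.05 over all tested genes with an absolute log2 fold change of at least 1. With 2 against 2 libraries a permutation test cannot give a two-sided p under 0.33, so none was used.

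The comparisons planned were EpiLC with ESC and PGCLC with EpiLC in WT, each line with WT at each stage, TKO with Ovol2KO and the Ovol2 transgenic lines with each other as PGCLC, and the differences between PGCLC and EpiLC effects for Ovol2KO, TKO, Ovol2a-Tg and Ovol2b-Tg. Comparisons of the transgenic lines with TKO were added after the values were seen. Overlaps between comparisons that share WT were set against independent sets and against 20 simulated fits. Their correlations and covariances were set against 100 simulations. No gene was changed in either.

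Gene lists were written from general knowledge in advance. Of 24 lists, 23 were tested: naive, general and formative pluripotency, germ cell, primitive streak and mesoderm, epithelial to mesenchymal transition, epithelial, Hox, WNT targets, BMP targets, neural, endoderm, trophoblast, endothelium and blood, fibroblast, early cleavage-stage, imprinted, p53, immediate early and heat shock, hypoxia and glycolysis, cholesterol synthesis, histone, and Y-linked genes with Xist. The lists held 431 genes, of which 372 were tested, and the mitochondrial list had no member in the table. Lists were tested with camera at a preset correlation of 0.01, adjusted by BH over the lists of a comparison, and again with an estimated correlation. Changed members were counted with p adjusted over all genes and adjusted over the list alone. Where the text gives a single count, both adjustments gave it.

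The genes named were set by a rule. Ovol1, Ovol2, Ovol3 and Cdh1 are always named. For each WT stage comparison and each PGCLC comparison, the 6 largest rises and 6 largest falls were eligible among changed genes whose libraries did not overlap and whose higher group had a mean TPM of at least 5, without predicted genes. Up to 4 changed members of each list, or 2 abundant members if none changed, were eligible as well. For ESC and EpiLC comparisons the rule took the 3 largest changes each way.

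The longest transcript of each of 13960 tested genes was aligned with minimap2 2.31 to all GENCODE M21 transcripts. A copy was a match to another gene at 95 percent identity or more over at least 50 percent of the transcript. Of the 13960 genes, 657 had a copy. The same 13960 genes were assigned to chromosomes, and medians of log2 fold change were taken per chromosome for genes with a mean TPM of at least 5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and for the figures.

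The tests were checked on simulated data. For PGCLC labelled Ovol2KO against WT, with 200 of 13148 genes changed, limma called 100 percent of 100 changes of 4 times and 47 percent of 100 changes of 2 times (92 percent of the latter passed the adjusted p alone), and 9 unchanged genes. A change of 2 times lies exactly at the fold threshold. The changed genes were drawn only from genes with many reads, with the same dispersion of 0.00568 for all, so these shares do not cover scarce genes. For PGCLC labelled TKO against WT, camera called a raised list of 20 genes and 0 of 23 unchanged lists. These lists held random genes that were simulated independently, so the check does not cover lists whose genes vary together.

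The comparisons were repeated with a fit of all 54 libraries, a fit of 2 stages only, a pseudocount of 0.1, no expression filter, quantile scaling, a block for the replicate number, camera with an estimated correlation, and leaving out each library in turn. Further repeats chosen after the values were seen used limma-voom on the recovered reads, averaging the Ovol2b-Tg EpiLC pair, and leaving out chromosomes 6, 8 and 16.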

Results

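Mouse embryonic stem cells (ESC) can be led through an epiblast-like state (EpiLC) to primordial germ cell-like cells (PGCLC), the first step of the germ line in culture. Here 9 lines were followed along that path: wild type (WT), lines labelled Ovol1KO, Ovol2KO, Ovol3KO and TKO, and lines labelled Ovol2a-Tg, Ovol2b-Tg, Ovol2a/2b-Tg and Cdh1-Tg. Ovol1, Ovol2 and Ovol3 encode zinc finger transcription factors, and Cdh1 encodes the adhesion protein E-cadherin. Each line was sampled as ESC, EpiLC and day 2 PGCLC with 2 libraries per group, giving 54 libraries in 27 groups. Expression of 14416 genes was compared with limma, and a gene was counted as changed when it passed both the BH adjusted p threshold of 0.05 and a log2 fold change of at least 1. Log2 fold changes are given with their standard errors and TPM values as mean ± SD of 2 libraries. The sources used here do not state that the 2 libraries of a group come from separate cultures, so the p-values measure only the spread between these samples. Gene lists and a rule for the genes to name were fixed before the data were examined, and genes outside the rule are said to be chosen after their values were seen.

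The line labelled Ovol2KO kept Ovol2 mRNA at every stage. Ovol2 stood at 14.7 ± 0.85 TPM in its ESC, 34.1 ± 0.59 in its EpiLC and 5.71 ± 1.4 in its PGCLC, against 7.81 ± 4, 11.1 ± 2.3 and 9.12 ± 3 in WT. In EpiLC labelled Ovol2KO the transcript was higher than in WT (log2 fold change 1.55 ± 0.12, limma, BH adjusted p = 3.88e-07). The log2 fold change of Ovol2 in PGCLC labelled Ovol2KO was −0.58 ± 0.27 (limma, BH adjusted p = 0.133). Ovol2 fell in PGCLC labelled TKO (−2.20 ± 0.27, limma, BH adjusted p = 2.12e-05), to 1.18 ± 0.48 TPM. Ovol3 was at 5.73 ± 0.097 TPM in EpiLC labelled Ovol3KO against 11.7 ± 1.9 in WT (−0.91 ± 0.15, limma, BH adjusted p = 0.000405), short of the fold threshold. In ESC of that label it stood at 10.2 ± 1.6 TPM against 8.91 ± 3.5 (0.21 ± 0.21, limma, BH adjusted p = 0.588), and in PGCLC at 8.55 ± 1.8 against 9.53 ± 0.19 (−0.15 ± 0.24, limma, BH adjusted p = 0.635). Ovol1 was scarce in every line, with 0.145 ± 0.21, 0.475 ± 0.068 and 1.15 ± 0.28 TPM in ESC, EpiLC and PGCLC labelled Ovol1KO and 0.427 ± 0.074, 0.692 ± 0.16 and 0.671 ± 0.49 in WT (log2 fold change in PGCLC 0.39 ± 0.25, limma, BH adjusted p = 0.447). The transgenic lines carried far more Ovol2 in PGCLC, at 884 ± 24 TPM in Ovol2a-Tg, 320 ± 35 in Ovol2b-Tg and 3300 ± 150 in Ovol2a/2b-Tg. Cdh1 in Cdh1-Tg PGCLC was 563 ± 0.92 TPM against 316 ± 5.7 in WT. A gene-level TPM does not show a deletion of part of a gene, so the knockout labels are taken from the titles, and these values do not settle them.

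**Figure D1:**
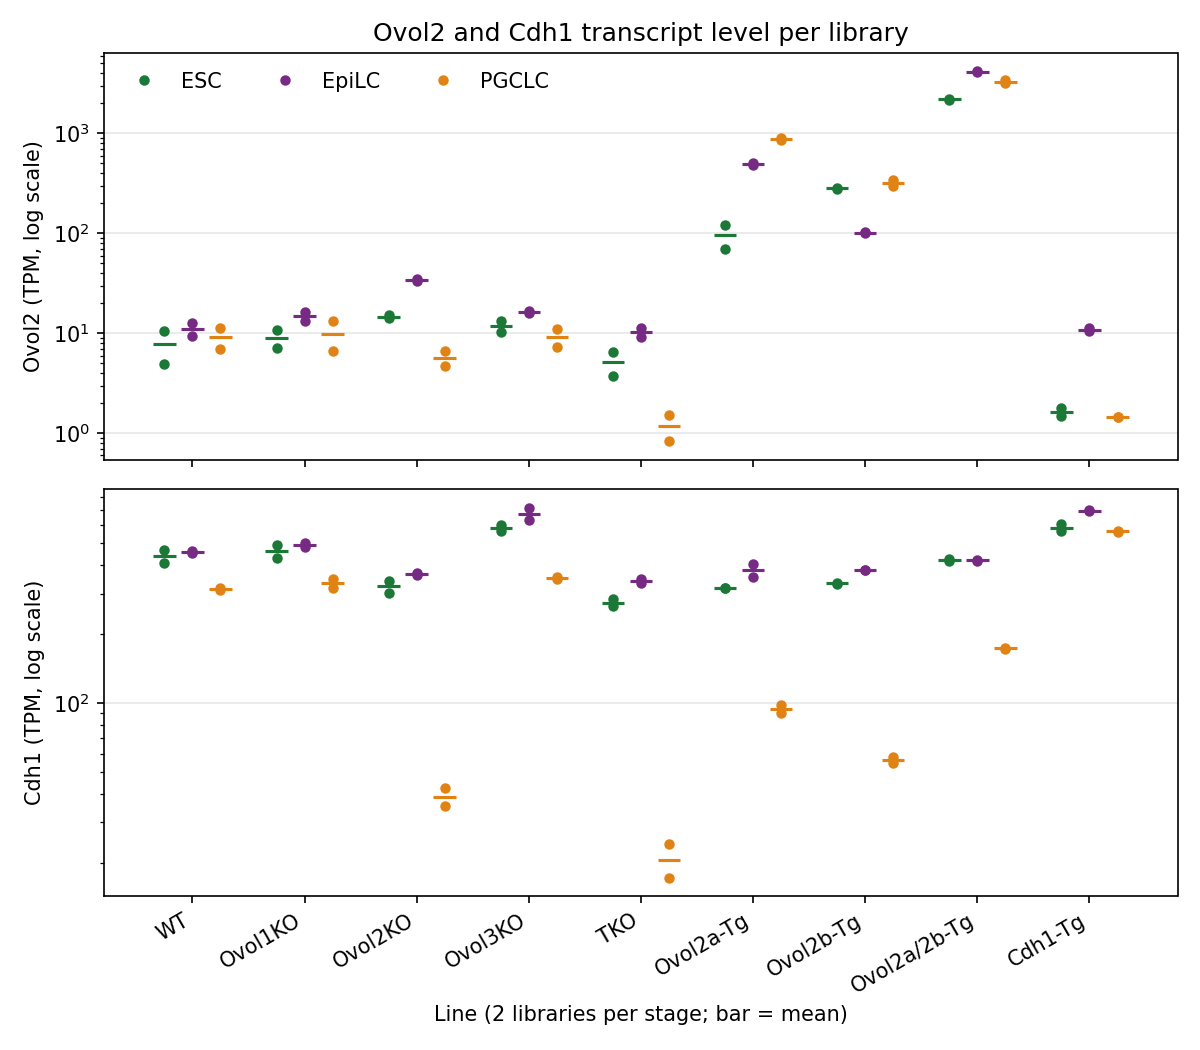
Ovol2 (upper panel) and Cdh1 (lower panel) in TPM for each library of the 9 lines at the ESC, EpiLC and PGCLC stages; bars are group means.

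Wild-type ESC lost the naive programme and took on a formative one on the way to EpiLC. Of 2964 changed genes, 1345 were higher and 1619 lower in EpiLC. Klf4 fell from 322 ± 10 to 1.67 TPM (log2 fold change −6.93 ± 0.22, limma, BH adjusted p = 6.07e-24), and Tbx3 (−6.58 ± 0.16) and Tfcp2l1 (−6.36 ± 0.22) fell with it. Fgf5 (6.11 ± 0.27), Pou3f1 (6.07 ± 0.20) and Pim2 (5.92 ± 0.26) rose, and Car4 reached 308 ± 13 TPM from being listed at 0. In the naive list 15 of 16 genes fell (median −4.62, camera BH adjusted p = 1.64e-16), and in the formative list 13 of 17 rose (median 3.29, camera BH adjusted p = 7.4e-15). Germ cell genes fell as well, 12 of 17 against 2 that rose (camera BH adjusted p = 7.11e-07). Among them Prdm14 fell from 42.6 TPM to 0.0232 and Tfap2c from 84.1 ± 2 to 1.15 ± 1.1. Cholesterol synthesis genes rose, 9 of 16 (camera BH adjusted p = 2.51e-07, adjusted p = 0.095 with an estimated correlation), with Lss at 1.74 ± 0.11 and Fdps at 1.36 ± 0.08. The p53 list had 1 rise and 5 falls (camera BH adjusted p = 0.0176, adjusted p = 0.239 with an estimated correlation). Fibroblast genes gave 6 rises (camera BH adjusted p = 0.00778, adjusted p = 0.239 with an estimated correlation), and immediate early genes gave 1 rise and 7 falls (camera BH adjusted p = 0.0403, adjusted p = 0.433 with an estimated correlation). The mesenchymal genes Vim (−2.91 ± 0.09) and Fn1 (−3.30 ± 0.16) fell, while Grhl2 (4.47 ± 0.17) and Krt18 (3.45 ± 0.22) of the epithelial list rose. Cdh1 had a log2 fold change of 0.05 ± 0.09 (limma, BH adjusted p = 0.644).

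No other list passed the camera threshold as a set between ESC and EpiLC, though several stood just above it. Rises and falls were 13 and 6 in the epithelial list (camera BH adjusted p = 0.055), 1 and 5 in the list of epithelial to mesenchymal transition (0.055), 4 and 4 in the primitive streak list (0.908) and 0 and 2 among Hox genes (0.679). They were 4 and 1 for general pluripotency (0.47), 3 and 3 for WNT targets (0.47), 1 and 3 for BMP targets (0.292), 1 and 1 for neural genes (0.306), 4 and 4 for endoderm (0.544) and 1 and 0 for trophoblast (0.801). Endothelium and blood gave 4 and 1 (0.237), imprinted genes 7 and 1 (0.0514), hypoxia and glycolysis 4 and 1 (0.47) and histone genes 6 and 0 (0.055). The lists of early cleavage-stage genes and of Y-linked genes with Xist stood at camera BH adjusted p = 0.983 and 0.385. Counts adjusted over the list alone were the same for all lists in this comparison.

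Day 2 PGCLC of WT had both germ cell and primitive streak transcripts. The streak regulator T had the largest rise, and Id1 rose from 1.52 ± 0.51 to 858 ± 67 TPM (log2 fold change 8.43 ± 0.31, limma, BH adjusted p = 1.7e-21), Cdx2 by 7.36 ± 0.32 and Fos by 7.85 ± 0.34. Against EpiLC 3043 genes changed, 1944 higher and 1099 lower. Quantile scaling, which removes a median shift of 0.148, gave 1383 higher and 1518 lower. In the primitive streak list 25 of 31 genes rose (median 3.88, camera BH adjusted p = 5.71e-15), and in the BMP target list 11 of 13 (median 3.23, camera BH adjusted p = 1.1e-08). Germ cell genes gave 11 rises and 1 fall (camera BH adjusted p = 0.00109), among them Tfap2c (4.48 ± 0.22), Prdm14 (3.74 ± 0.15) and Prdm1 (3.58 ± 0.17). Formative genes fell, 13 of 17 against 1 rise (camera BH adjusted p = 3.6e-08), with Pou3f1 at −4.91 ± 0.20 and Dnmt3l at −3.88 ± 0.19. Cholesterol synthesis genes fell, 14 of 16 (camera BH adjusted p = 6.1e-18), led by Fdps (−2.35 ± 0.08). WNT targets gave 11 rises and 1 fall (camera BH adjusted p = 2.54e-06), with Sp5 at 6.47 ± 0.20 and Axin2 at 4.90 ± 0.17. Hox genes gave 11 rises (camera BH adjusted p = 0.00244, adjusted p = 0.211 with an estimated correlation), including Hoxb1 and Hoxb2, both listed at 0 in EpiLC. In the transition list 14 of 23 genes rose (camera BH adjusted p = 1.88e-05, adjusted p = 0.0878 with an estimated correlation), among them Cdh2 (3.86 ± 0.21), Snai1 (3.64 ± 0.31) and Vim (3.62 ± 0.09). The epithelial list gave 7 rises and 5 falls (camera BH adjusted p = 0.854). Counts adjusted over the list alone were the same for these lists.

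PGCLC labelled Ovol2KO lost epithelial transcripts and gained posterior and mesenchymal ones. Cldn7 fell from 152 ± 20 to 2.31 ± 0.052 TPM (log2 fold change −5.53 ± 0.24, limma, BH adjusted p = 9.08e-10), Cldn6 from 182 ± 35 to 1.1 ± 1.6 TPM, and Cdh1 from 316 ± 5.7 to 38.8 ± 4.9 TPM (−3.00 ± 0.11, limma, BH adjusted p = 2.49e-10). Cldn4 (−5.26 ± 0.30) and Ap1m2 (−5.19 ± 0.27) fell with them. Hoxb6 rose from 0.278 to 29.3 ± 7 TPM (4.55 ± 0.44, limma, BH adjusted p = 3.61e-06), next to Cdx4 (4.51 ± 0.31), Hoxd9 (3.72 ± 0.34) and Hoxb8 (2.87 ± 0.31). Compared with WT PGCLC, 1179 genes changed, 592 higher and 587 lower, or 554 and 591 with quantile scaling. In the epithelial list 24 of 31 genes fell, the same count when adjusted over the list alone (median −2.28, camera BH adjusted p = 3.16e-24). In the Hox list 22 of 27 rose, also when adjusted over the list alone (median 1.86, camera BH adjusted p = 1.62e-14). Mesenchymal regulators rose too: Zeb1 from 0.697 to 10.4 ± 0.03 TPM, Twist2 by 3.31 ± 0.31 and Cdh11 by 2.08 ± 0.19. The transition list held 13 rises and 1 fall, unchanged when adjusted over the list alone (camera BH adjusted p = 7.02e-09, adjusted p = 0.0984 with an estimated correlation).

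Pluripotency genes were lower in PGCLC labelled Ovol2KO. Utf1 fell by 3.76 ± 0.27, Esrrb by 2.76 ± 0.28, Zfp42 by 2.74 ± 0.26 and Otx2 by 2.51 ± 0.26. The naive list had 11 falls (camera BH adjusted p = 5.09e-10, adjusted p = 0.0819 with an estimated correlation) and the general pluripotency list 8 of 11 (camera BH adjusted p = 2.27e-06, adjusted p = 0.0867 with an estimated correlation). Dppa3 fell from 19.2 ± 1.7 to 2.39 ± 0.43 TPM and Tdrd5 from 37.5 ± 3.9 to 4.78 ± 0.15, but the germ cell list as a set had 2 rises and 6 falls, with 7 falls when adjusted over the list alone (camera BH adjusted p = 0.0634). Mesoderm was split. Foxf1 (3.53 ± 0.21), Hand1 (3.35 ± 0.47) and Isl1 (2.70 ± 0.45) rose, and Eomes fell from 52.7 ± 13 to 1.83 ± 0.66 TPM (−4.25 ± 0.31, limma, BH adjusted p = 2.46e-07). The primitive streak list had 9 rises and 3 falls, 10 rises when adjusted over the list alone (camera BH adjusted p = 0.0675). Cholesterol synthesis genes rose, 12 of 16 (camera BH adjusted p = 5.33e-17), such as Mvd (1.42 ± 0.11) and Hmgcs1 (1.34 ± 0.08). The p53 list had 2 falls (camera BH adjusted p = 1.7e-08), one of them Perp (−1.68 ± 0.13).

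PGCLC labelled TKO shared the loss of epithelial identity seen in those labelled Ovol2KO. Cdh1 dropped to 20.6 ± 4.9 TPM (log2 fold change −3.89 ± 0.11, limma, BH adjusted p = 2.16e-11), Cldn7 to 0.988 ± 0.86 (−6.34 ± 0.24, limma, BH adjusted p = 2.73e-10) and Esrp1 to 0.697 ± 0.71 (−5.03 ± 0.24). Nanog fell from 185 ± 18 to 26.5 ± 0.83 TPM, Sox2 by 2.37 ± 0.21 and Pou5f1 by 1.83 ± 0.09. Plac1 (5.78 ± 0.38), Cdx4 (5.26 ± 0.31), Hoxb6 (4.81 ± 0.44) and Col1a1 (4.48 ± 0.33) rose. In all, 1518 genes changed against WT, 804 higher and 714 lower, an excess of rises that turned under quantile scaling (726 and 741) and limma-voom (1005 and 1016). Epithelial genes fell in 25 cases out of 31, the same when adjusted over the list alone (median −2.61, camera BH adjusted p = 1.1e-23), and the Hox list 23 rises out of 27, again the same when adjusted over the list alone (median 2.4, camera BH adjusted p = 2.11e-13). Germ cell genes differed among themselves, with Dppa3 (−3.48 ± 0.26), Tdrd5 (−3.57 ± 0.29) and Tfap2c (−1.67 ± 0.20) lower and Ifitm1 (1.62 ± 0.11) higher (list camera BH adjusted p = 0.215). Vascular genes rose, for example Cxcr4 (3.09 ± 0.22) and Tal1 (1.70 ± 0.21), 5 in the endothelium and blood list (camera BH adjusted p = 0.00562, adjusted p = 0.0727 with an estimated correlation). The transition list gave 15 rises (camera BH adjusted p = 3.42e-11, adjusted p = 0.0727 with an estimated correlation), with Zeb1 at 2.99 ± 0.23, Twist2 at 3.59 ± 0.31 and Snai2 at 2.60 ± 0.41.

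Genes changed in both of these knockout-labelled lines went the same way: 475 were higher in both (33 for independent sets), 467 lower in both (29.1 for independent sets) and 2 opposite. The log2 fold changes correlated at 0.86, against 0.5 in simulations where only the WT libraries were shared. Their covariance was 0.365, against 0.023 in those simulations. The simulated overlaps were 0, but with no gene changed an overlap of calls could hardly arise, so they do not measure the part of shared WT. Both comparisons use the same 2 WT libraries, so part of the excess may come from them. Compared directly, PGCLC labelled TKO and Ovol2KO differed in 142 genes, 103 higher and 39 lower in TKO. Leaving out replicate 2 of the Ovol2KO pair gave 79. Erdr1 (log2 fold change 10.66 ± 0.42) and Mid1 (6.18 ± 0.08) were higher in TKO, as was Snrpn, at 93.6 TPM against 0.179 in Ovol2KO (6.34 ± 0.13, limma, BH adjusted p = 4.45e-14). In WT PGCLC Erdr1, Mid1 and Snrpn stood at 1970, 591 and 152 TPM. TKO was nearer to these levels (2660, 619 and 93.6) than Ovol2KO was (0.85, 7.55 and 0.179). Cdx1 fell from 278 to 101 TPM (−1.45 ± 0.22, limma, BH adjusted p = 0.00175) and Hoxc9 rose from 1.07 to 4.65 TPM (1.45 ± 0.19, limma, BH adjusted p = 0.000343). Cdh1 was 0.90 ± 0.11 lower in TKO (limma, BH adjusted p = 0.000257), short of the fold threshold. Among epithelial genes there was 1 fall, or 3 when adjusted over the list alone (median −0.32, camera BH adjusted p = 9.1e-05).

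PGCLC labelled Ovol1KO differed from WT in few called genes in the main fit, with Y-linked genes among them. Genes on chromosome 16 were higher as a group (median log2 fold change 0.32). Eif2s3y fell from 27 ± 0.8 to 1.22 ± 0.47 TPM (log2 fold change −3.67 ± 0.24, limma, BH adjusted p = 2.88e-06) and Uty by 2.23 ± 0.20. The neurofilament gene Nefm fell from 25.8 ± 1.8 to 6.16 ± 0.13 TPM (−1.90 ± 0.19, limma, BH adjusted p = 0.00017). Counted over all genes, 96 changed, 71 higher and 25 lower. The count hangs on single libraries, at 13 without replicate 1 of Ovol1KO, 489 without its replicate 2, 18 without replicate 1 of WT and 35 without replicate 2 of WT. Naive genes were higher as a set, with 4 rises, or 6 when adjusted over the list alone (median 0.85, camera BH adjusted p = 7.39e-07, adjusted p = 0.276 with an estimated correlation). The rises of Spp1 (1.44 ± 0.21), Dnmt3l (1.70 ± 0.26) and Dppa3 (1.26 ± 0.26) were no longer called without replicate 1 of Ovol1KO. The epithelial list had a median of 0.08 (camera BH adjusted p = 0.6) and the Hox list one of −0.26 (camera BH adjusted p = 0.0574), and Cdh1 stood at 0.08 ± 0.11 (limma, BH adjusted p = 0.774).

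PGCLC labelled Ovol3KO departed from WT in another direction, with more pluripotency and less primitive streak expression. Dnmt3l rose from 4.76 ± 0.4 to 108 ± 12 TPM (log2 fold change 4.24 ± 0.26, limma, BH adjusted p = 1.5e-08), Dppa3 from 19.2 ± 1.7 to 178 ± 7.2 (3.15 ± 0.26, limma, BH adjusted p = 2.32e-07), Utf1 by 2.51 ± 0.27 and Foxd3 by 3.20 ± 0.29. Mixl1 fell from 267 ± 28 to 9.23 ± 5 TPM (−4.80 ± 0.36, limma, BH adjusted p = 1.05e-06) and Mesp1 from 69.2 ± 26 to 0.894 ± 1.3, while Msgn1 was listed at 0 against 140 ± 49 in WT. Of 1850 changed genes, 625 were higher and 1225 lower. Quantile scaling, which removes a median shift of −0.115, gave 866 higher and 933 lower. In the primitive streak list 25 of 31 genes fell, the same when adjusted over the list alone (median −2.37, camera BH adjusted p = 2.12e-10, adjusted p = 0.217 with an estimated correlation). In the naive list 14 of 16 rose, also the same when adjusted over the list alone (median 2.2, camera BH adjusted p = 6.93e-09, adjusted p = 0.217 with an estimated correlation). WNT targets gave 9 falls, among them Lef1 (−2.72 ± 0.16), and BMP targets 6, among them Msx1 (−3.52 ± 0.17), Msx2 (−3.22 ± 0.26) and Id1 (−1.63 ± 0.12). Cdh2 (−3.46 ± 0.27), Snai1 (−2.65 ± 0.16), Vim (−2.27 ± 0.11), Krt8 (−2.81 ± 0.23), Hoxb1 (−4.12 ± 0.30) and Gata3 (−3.58 ± 0.21) fell. Cdh1 was 352 ± 5.2 TPM (0.16 ± 0.11, limma, BH adjusted p = 0.29). Genes changed in both the Ovol2KO and Ovol3KO lines were mostly opposite, 302, against 23 higher in both (25.7 for independent sets) and 98 lower in both (49.9 for independent sets). The log2 fold changes over all genes had a correlation of −0.17 and a covariance of −0.076 (0.5 and 0.023 in the simulations). The simulations gave no overlap, but with no gene changed one could hardly arise.

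**Figure D2:**
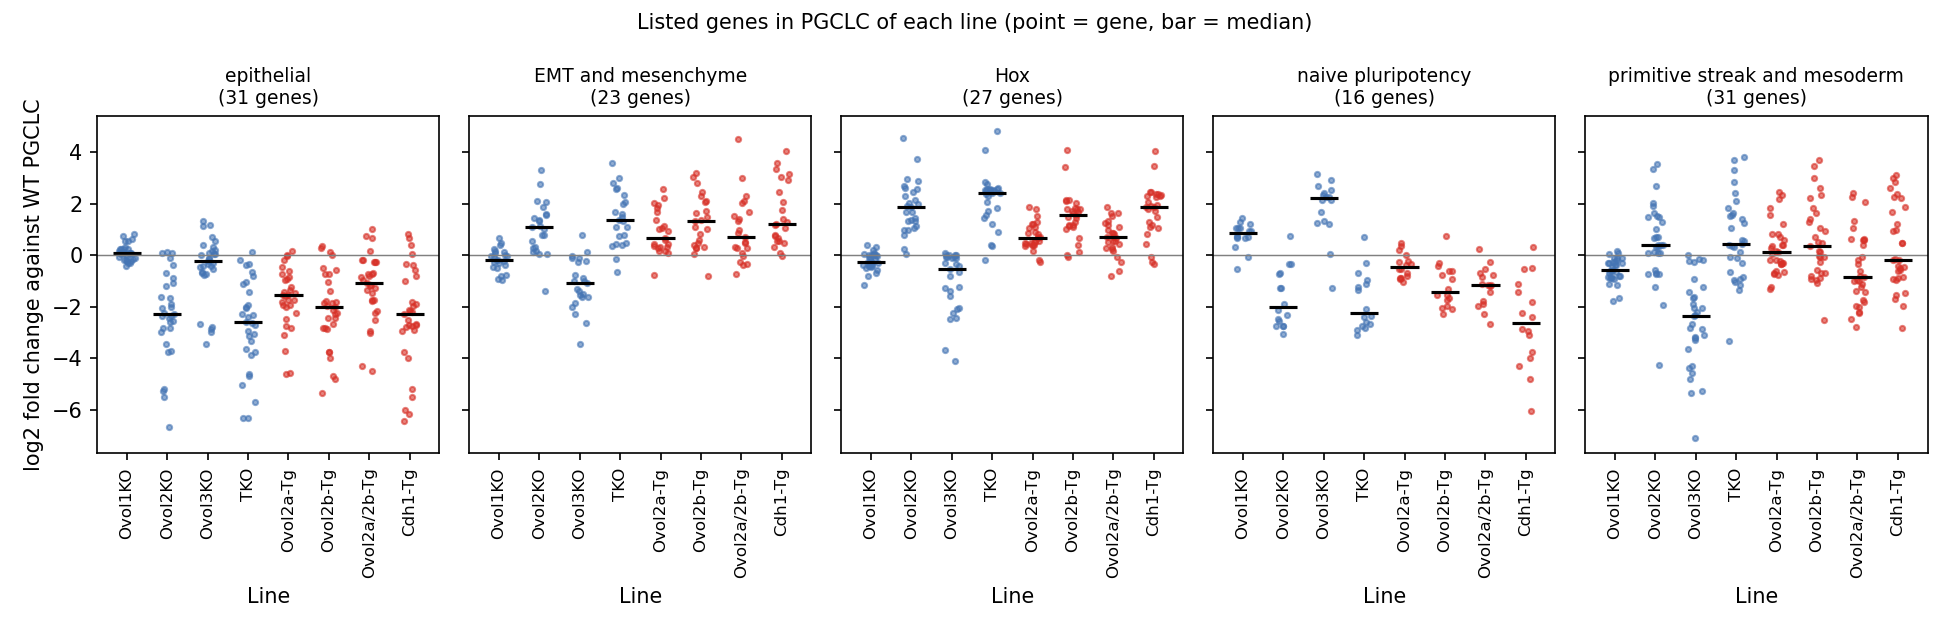
Log2 fold change against WT PGCLC for each gene of the epithelial, epithelial to mesenchymal transition, Hox, naive pluripotency and primitive streak lists in 8 lines; bars are medians, knockout-labelled lines in blue and transgenic lines in red.

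All 3 Ovol2 transgenic lines also had fewer epithelial transcripts than WT as PGCLC. In Ovol2a-Tg Ovol2 was 6.48 ± 0.27 above WT on the log2 scale (limma, BH adjusted p = 1.14e-08), Ap1m2 fell from 112 ± 8.4 to 3.64 TPM, Cldn7 from 152 ± 20 to 5.38 TPM, and Cdh1 by 1.73 ± 0.11 (limma, BH adjusted p = 2.86e-07). Mest (3.22 ± 0.24), Foxf1 (2.47 ± 0.21), Zeb1 (2.04 ± 0.23) and Hoxa5 (1.81 ± 0.22) rose. The change reached 494 genes, 302 higher and 192 lower, or 290 without replicate 2 of Ovol2a-Tg. The epithelial list had 21 falls out of 31, the same when adjusted over the list alone (median −1.56, camera BH adjusted p = 1.32e-27), and the Hox list 8 rises (camera BH adjusted p = 4.86e-06, adjusted p = 0.163 with an estimated correlation). Ovol2b-Tg changed more, 1197 genes, 744 higher and 453 lower. There Ovol2 was higher by 5.02 ± 0.27, Hoxb6 by 4.08 ± 0.44, Foxf1 by 3.70 ± 0.21, Hand1 by 3.46 ± 0.47 and Twist1 by 2.44 ± 0.15. Cldn7 (−5.34 ± 0.24), Esrp1 (−4.00 ± 0.24), Utf1 (−2.56 ± 0.27), Cdh1 (−2.46 ± 0.11) and Dppa3 (−2.38 ± 0.26) fell in Ovol2b-Tg. Its epithelial list had 23 falls (median −2.02, camera BH adjusted p = 5.5e-21) and its Hox list 22 rises (median 1.57, camera BH adjusted p = 3.62e-10, adjusted p = 0.0723 with an estimated correlation), the same counts when adjusted over the list alone.

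Ovol2a/2b-Tg PGCLC, with the most Ovol2, had fewer epithelial and immediate early transcripts than WT. Ovol2 was 8.38 ± 0.27 above WT (limma, BH adjusted p = 8.08e-11) and Cdh1 0.86 ± 0.11 below it (limma, BH adjusted p = 4.04e-05), short of the fold threshold, at 174 ± 0.38 TPM. Fos fell from 596 ± 99 to 6.32 ± 0.94 TPM, Egr1 from 245 to 2.44 ± 0.8 and Grb10 from 212 to 4.17 ± 0.52. Fos and Egr1 were at 9.77 ± 3.9 and 38.7 ± 2.3 TPM in ESC of this line against 57.9 ± 2.1 and 253 ± 43 in WT ESC, and at 18.4 ± 7.7 and 12 ± 6.5 TPM in Cdh1-Tg PGCLC. Hist2h2ab was listed at 0 against 48 ± 13 in WT PGCLC. Tgfbi (4.53 ± 0.28), Acta2 (2.28 ± 0.18) and Twist1 (2.10 ± 0.15) rose, while Eomes (−2.79 ± 0.31), Klf2 (−2.68 ± 0.23) and Id1 (−1.90 ± 0.12) fell. Altogether 1099 genes changed against WT, 674 higher and 425 lower. Epithelial genes gave 16 falls and 1 rise (median −1.07, camera BH adjusted p = 5.73e-09), the immediate early list 8 falls (median −2.25, camera BH adjusted p = 6.43e-06, adjusted p = 0.169 with an estimated correlation) and the naive list 10 falls (camera BH adjusted p = 2.89e-07, adjusted p = 0.169 with an estimated correlation). The primitive streak list split into 5 rises and 14 falls (camera BH adjusted p = 0.00844, adjusted p = 0.585 with an estimated correlation). Counts adjusted over the list alone were the same for these 4 lists.

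The Ovol2 transgenic lines differed from each other in the level of Ovol2 and, among other genes, in some epithelial and posterior ones. Between Ovol2a-Tg and Ovol2b-Tg PGCLC 134 genes differed, 53 higher and 81 lower in Ovol2a-Tg, but 25 without replicate 1 of Ovol2a-Tg, 225 without its replicate 2 and 77 without replicate 2 of Ovol2b-Tg. The direction of the majority turned with a pseudocount of 0.1 (71 higher, 50 lower) and with limma-voom (271 higher, 224 lower). Mid1 (6.79 ± 0.08) and Chrna9 (4.09 ± 0.34) were higher in Ovol2a-Tg, and Tbx4 (−2.22 ± 0.30), Igf2 (−2.12 ± 0.29), Hoxa10 (−1.73 ± 0.24) and Kit (−1.51 ± 0.21) lower. Mid1 stood at 943 TPM in Ovol2a-Tg, 591 in WT and 7.56 in Ovol2b-Tg. Hox genes were lower as a set, 8 genes or 9 when adjusted over the list alone (median −0.62, camera BH adjusted p = 4.9e-09, adjusted p = 0.0785 with an estimated correlation). The epithelial list was higher, 3 genes by either adjustment, all genes or adjusted over the list alone (median 0.46, camera BH adjusted p = 2.7e-06). Ovol2a/2b-Tg differed from Ovol2a-Tg in 345 genes, 191 higher and 154 lower (211 and 225 with a pseudocount of 0.1), and from Ovol2b-Tg in 745, 342 higher and 403 lower (639 and 615 with limma-voom). Against Ovol2b-Tg, the combined line had more Cdh1 (1.61 ± 0.11, limma, BH adjusted p = 2.93e-07), Cldn4 (2.00 ± 0.30), Grhl2 (1.74 ± 0.20) and Grhl3 (1.68 ± 0.27), 15 epithelial rises in all, the same when adjusted over the list alone (median 0.83, camera BH adjusted p = 1.5e-08). Against Ovol2a-Tg the epithelial list had 1 rise, the same when adjusted over the list alone (median 0.63, camera BH adjusted p = 2.8e-05). The combined line had more Grhl2 than Ovol2a-Tg (1.28 ± 0.20) and less Dll3 (−2.64 ± 0.24), Klf2 (−1.62 ± 0.23) and Klf4 (−1.59 ± 0.24). The immediate early list had 8 falls against Ovol2a-Tg (median −1.56, camera BH adjusted p = 2.24e-06, adjusted p = 0.241 with an estimated correlation) and 8 against Ovol2b-Tg (median −1.75, camera BH adjusted p = 1.05e-05, adjusted p = 0.22 with an estimated correlation), the same when adjusted over the list alone. Primitive streak genes were lower in the combined line than in Ovol2b-Tg, 15 or 17 when adjusted over the list alone (median −1.19, camera BH adjusted p = 3.17e-08, adjusted p = 0.223 with an estimated correlation), among them Tbx6 (−2.20 ± 0.30).

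Set against PGCLC labelled TKO, a comparison chosen after the values were seen, the Ovol2 lines held more epithelial transcripts, to unlike degrees. Cdh1 was higher by 2.16 ± 0.11 in Ovol2a-Tg (limma, BH adjusted p = 5.68e-08), 1.43 ± 0.11 in Ovol2b-Tg (limma, BH adjusted p = 9.38e-06) and 3.03 ± 0.11 in Ovol2a/2b-Tg (limma, BH adjusted p = 1.38e-10). Ovol2a-Tg also had more Utf1 (3.11 ± 0.27), Dppa3 (2.65 ± 0.26), Nr0b1 (2.47 ± 0.27), Esrp1 (2.29 ± 0.24) and Sox2 (1.77 ± 0.21), and less Hoxb6 (−3.28 ± 0.44) and Cdx4 (−3.03 ± 0.31). It differed from TKO in 475 genes, 272 higher and 203 lower, or 215 without replicate 1 of Ovol2a-Tg. Epithelial genes were higher in 16 of 31 (median 1.06, camera BH adjusted p = 2.78e-15), the same when adjusted over the list alone, and Hox genes lower in 18, or 19 when adjusted over the list alone (median −1.37, camera BH adjusted p = 6.19e-16). Ovol2b-Tg lay near TKO, with 51 changed genes, 33 higher and 18 lower, or 11 without its replicate 2, 109 without its replicate 1 and 26 without replicate 1 of TKO. Its epithelial list had 3 rises, 5 when adjusted over the list alone (median 0.63, camera BH adjusted p = 1.62e-13), and Igf2 rose by 2.82 ± 0.29. Ovol2a/2b-Tg differed in 1207 genes, 624 higher and 583 lower (597 and 604 with quantile scaling), with Cldn4 (2.93 ± 0.30), Tdrd5 (2.37 ± 0.29), Dppa3 (2.39 ± 0.26), Sox2 (2.08 ± 0.21) and Pou5f1 (1.41 ± 0.09) higher and Dll3 (−3.56 ± 0.24), Hoxb6 (−3.17 ± 0.44) and Tbx6 (−2.37 ± 0.30) lower. Its epithelial list had 20 rises (median 1.38, camera BH adjusted p = 7.91e-13), the same when adjusted over the list alone. Fold changes of the lines over TKO ran against those of Ovol2KO over WT, which share no library, with correlations of −0.65 for Ovol2a-Tg, −0.23 for Ovol2b-Tg and −0.44 for Ovol2a/2b-Tg. For Ovol2a-Tg 193 genes higher in the line and 152 lower were opposite in the 2 comparisons (11.1 and 8.3 for independent sets), and 2 went the same way (19.4). For Ovol2a/2b-Tg these were 222 and 216 opposite (25.4 and 23.9) with 24 the same way (49.4), and for Ovol2b-Tg 15 and 6 (1.3 and 0.7) with 7 the same way (2.1). Cdh1-Tg, at a correlation of −0.13, had 29 and 30 opposite (5.8 and 7.7) but 31 the same way (13.5).

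Cdh1-Tg PGCLC combined high Cdh1 with few other epithelial transcripts. Cdh1 stood at 563 ± 0.92 TPM (log2 fold change against WT 0.83 ± 0.11, limma, BH adjusted p = 4.25e-05, short of the fold threshold), yet Cldn6 fell from 182 ± 35 to 1.2 TPM, Cldn7 from 152 ± 20 to 1.13 and Cldn4 from 89.4 ± 5.8 to 1.01. Ovol2 fell to 1.46 TPM (−2.01 ± 0.27, limma, BH adjusted p = 4.71e-05). Pluripotency genes were low, with Utf1 at −4.74 ± 0.27, Esrrb at −4.31 ± 0.28 and Dppa3 at −4.06 ± 0.26, and Zeb1 (3.33 ± 0.23), Tgfbi (4.03 ± 0.28), Unc5c (4.51 ± 0.26) and Hoxb6 (4.06 ± 0.44) rose. Against WT 1421 genes changed, 801 higher and 620 lower, but the excess of rises nearly vanished with quantile scaling (685 and 678) and turned with limma-voom (978 and 1079). The epithelial list had 23 falls (median −2.28, camera BH adjusted p = 4.52e-19), the naive list 13 (median −2.64, camera BH adjusted p = 8.99e-13, adjusted p = 0.0801 with an estimated correlation) and the Hox list 22 rises (median 1.88, camera BH adjusted p = 7.27e-09, adjusted p = 0.0874 with an estimated correlation), the same counts when adjusted over the list alone. Against TKO, again chosen after the values were seen, 331 genes differed, 143 higher and 188 lower (238 and 236 with a pseudocount of 0.1). Cdh1 led the rises (4.72 ± 0.11, limma, BH adjusted p = 1.24e-12). Prdm1 (1.85 ± 0.21) and Tfap2c (1.19 ± 0.20), named as members of the germ cell list and not by rank, rose far less. Against TKO the epithelial list had 1 rise, the same when adjusted over the list alone (median 0.07, camera BH adjusted p = 0.287). Fos (−4.22 ± 0.41), Egr1 (−4.09 ± 0.27) and the naive genes Klf4 (−1.70 ± 0.24) and Klf2 (−1.60 ± 0.23) were lower than in TKO.

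As EpiLC, the lines labelled Ovol2KO and TKO and the 4 transgenic lines kept most or all of their Cdh1 but already carried a weaker epithelial profile, which those labelled Ovol1KO and Ovol3KO did not. Vim rose in EpiLC labelled Ovol2KO from 40.5 ± 5.2 to 214 TPM (log2 fold change 2.38 ± 0.07, limma, BH adjusted p = 3.02e-12), in those labelled TKO to 235 TPM (2.51 ± 0.07, limma, BH adjusted p = 2.66e-12), and in Ovol2b-Tg and Cdh1-Tg to 229 and 278 TPM. In TKO Zeb1 rose by 2.28 ± 0.15, Ap1m2 fell by 4.45 ± 0.17 and Cldn7 by 3.38 ± 0.08. Cdh2 rose by 2.53 ± 0.17 in Cdh1-Tg, and Snai2 by 2.28 ± 0.25 in Ovol2b-Tg. The epithelial list had 8 falls and 1 rise in Ovol2KO (camera BH adjusted p = 8.51e-28), 11 falls in TKO (1.13e-25), 8 in Ovol2a-Tg (3.38e-20), 8 in Ovol2b-Tg (9.28e-25), 6 in Ovol2a/2b-Tg (8.72e-09) and 13 in Cdh1-Tg (8.22e-12), and 3 rises in Ovol3KO (0.00158, adjusted p = 0.101 with an estimated correlation). Those counts were the same when adjusted over the list alone. In Ovol1KO the median of the list was 0.07 (camera BH adjusted p = 0.961). EpiLC labelled Ovol3KO had more Mcam (2.44 ± 0.12), Gdf15 (2.43 ± 0.25) and Esrrb (2.39 ± 0.18).

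The number of changed genes in EpiLC was 70 in Ovol1KO (45 higher, 25 lower), 205 in Ovol2KO (82, 123), 411 in Ovol3KO (249, 162), 331 in TKO (211, 120), 297 in Ovol2a-Tg (219, 78), 241 in Ovol2b-Tg (166, 75), 649 in Ovol2a/2b-Tg (321, 328) and 920 in Cdh1-Tg (522, 398). Without replicate 2 of WT EpiLC these became 161 in Ovol1KO, 344 in Ovol2KO, 696 in Ovol3KO, 516 in TKO, 481 in Ovol2a-Tg and 439 in Ovol2b-Tg. Ovol1KO gave 38 without replicate 1 of WT EpiLC, and Ovol3KO 637 without its own replicate 2. The Ovol2b-Tg EpiLC pair varied hardly beyond read sampling, so its libraries may not be separate samples, and averaged to 1 library it gave 193 changed genes. Quantile scaling changed the split of higher and lower genes to 22 and 30 in Ovol1KO, 51 and 141 in Ovol2KO, 124 and 163 in TKO, 139 and 113 in Ovol2a-Tg, 94 and 123 in Ovol2b-Tg and 368 and 507 in Cdh1-Tg. Limma-voom gave 430 and 493 in Ovol3KO and 656 and 614 in Ovol2a/2b-Tg, where the pseudocount of 0.1 gave 715 and 543.

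Undifferentiated ESC of the lines also had fewer epithelial transcripts in most cases. In ESC labelled TKO Cldn7 fell from 53 to 2.28 TPM (log2 fold change −4.06 ± 0.18, limma, BH adjusted p = 5.1e-09) and Krt8 from 21.6 to 0.935, while Lef1 rose from 1.54 ± 0.23 to 26.5 TPM (3.44 ± 0.23, limma, BH adjusted p = 1.35e-07). Lef1 rose in Ovol2b-Tg (3.07 ± 0.23) and Cdh1-Tg (3.84 ± 0.23) as well, and Cdh1-Tg lost Egr1 (−4.42 ± 0.22), Ap1m2 (−4.24 ± 0.22) and Cldn7 (−4.12 ± 0.18). ESC labelled Ovol2KO had more Bmp4 (2.73 ± 0.38) and Etv1 (2.19 ± 0.30), those labelled Ovol3KO more Etv4 (2.98 ± 0.29) and Spry4 (2.34 ± 0.24), and those labelled Ovol1KO less Nefm (−3.52 ± 0.21). The epithelial list had 16 falls in Ovol2KO (camera BH adjusted p = 4.6e-14), 13 in TKO (3.54e-12), 16 in Ovol2b-Tg (8.09e-11), 10 in Ovol2a/2b-Tg (2.94e-05), 17 with 1 rise in Cdh1-Tg (1.03e-10) and 6 in Ovol2a-Tg (0.0395, adjusted p = 0.276 with an estimated correlation), the same when adjusted over the list alone. Changed genes numbered 78 in Ovol1KO (42 higher, 36 lower), 484 in Ovol2KO (111, 373), 266 in Ovol3KO (94, 172), 588 in TKO (231, 357), 714 in Ovol2a-Tg (360, 354; 336 and 347 with no expression filter), 801 in Ovol2b-Tg (250, 551), 622 in Ovol2a/2b-Tg (213, 409) and 922 in Cdh1-Tg (289, 633). For Ovol1KO the count was 45 without replicate 2 of WT ESC, 133 without its own replicate 1 and 49 without its own replicate 2. Quantile scaling changed the split of higher and lower genes to 27 and 45 in Ovol1KO, 159 and 266 in Ovol2KO, 299 and 296 in TKO, 333 and 364 in Ovol2b-Tg and 367 and 517 in Cdh1-Tg.

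Several lines differed from WT along whole chromosomes, which was found after the values were seen. Genes on chromosome 16 had a median log2 fold change of 0.49 to 0.52 over the 3 stages in TKO, 0.48 to 0.54 in the 4 transgenic lines and 0.32 at every stage in Ovol1KO, against −0.03 to 0.02 in Ovol2KO. In Ovol3KO the median on chromosome 8 was 0.452 in ESC, 0.467 in EpiLC and 0.452 in PGCLC, and on chromosome 6 it was 0.345, 0.343 and 0.186. Ovol1KO had a smaller rise on chromosome 8, with medians of 0.09, 0.105 and 0.115 in the same order. Leaving out chromosomes 6, 8 and 16 gave 1282 changed genes in PGCLC labelled TKO, 1604 in those labelled Ovol3KO, 83 in those labelled Ovol1KO and 124 between TKO and Ovol2KO. The sex-linked and imprinted genes also separated the lines. Y-linked Eif2s3y was at 27 TPM in WT PGCLC and lower in every other line, at 5.68 in Ovol3KO, 1.35 in Ovol2a-Tg, 1.22 in Ovol1KO, 0.85 in TKO, 0.503 in Cdh1-Tg and 0.149 in Ovol2a/2b-Tg, and listed at 0 in Ovol2KO and Ovol2b-Tg. Mid1 fell from 591 to 7.55 TPM in Ovol2KO and 7.56 in Ovol2b-Tg, and Snrpn was at 0.179 TPM in Ovol2KO alone. Nnat was at 26.5 TPM in WT, 46.1 in Ovol2KO, 3.69 in TKO and 0.463 to 2.93 in the transgenic lines. Of the genes named in this text, Dppa3, Twist2, Igf2, Hist2h2ab, Hist2h2ac, Acot10, Rpl37rt, Zscan4c and Zscan4f have near-identical copies among the transcripts at 95 percent identity, G6pd2 and Rasl2-9 have copies at 90 percent only, and no transcript was matched for Erdr1, so their values are uncertain. Of the 17 genes shared by Ovol2a/2b-Tg and Cdh1-Tg that are named below, only 16 had a matched transcript.

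**Figure D3:**
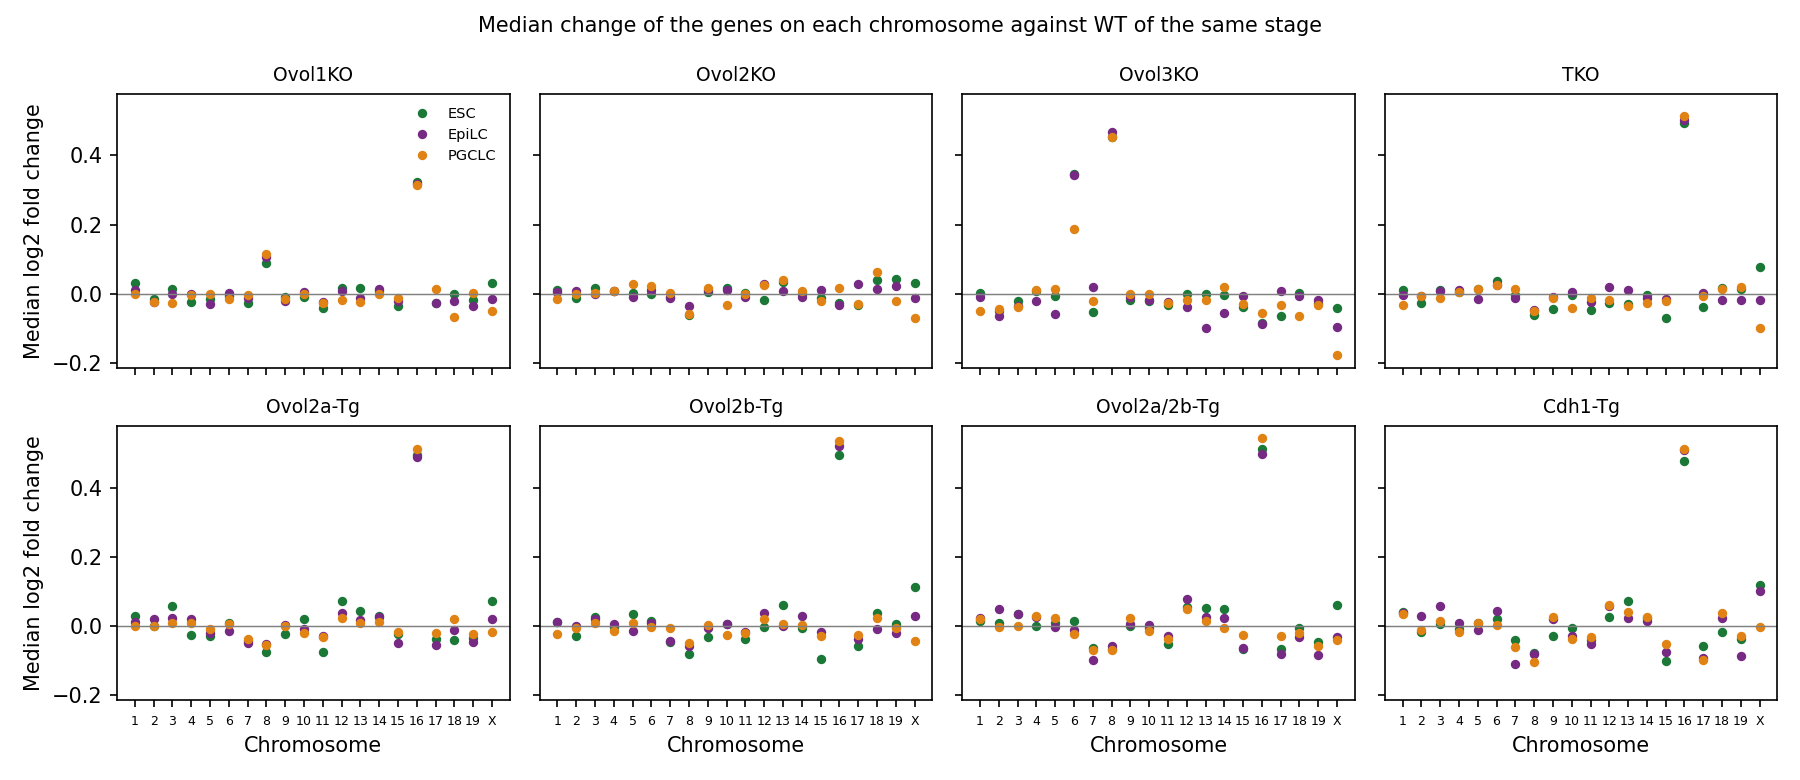
Median log2 fold change of the genes on each of 20 chromosomes against WT of the same stage, in 8 lines at the ESC, EpiLC and PGCLC stages.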

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

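The tests of library batches for the nearness to TKO, of chromosome doses, of a TKO background in ESC, of depth (both tests) and of gene copies were chosen only after the result was seen. The first versions of the other tests compared single values with a bound, and confidence intervals were added after the values were known. By the bounds alone a TKO background in PGCLC and carry-over from EpiLC would have been excluded, and carry-over from ESC, a wrong label and a library batch for the genes shared by 2 lines would have met what was predicted. The test of chromosomes 6 and 8 first pooled rises and falls (10.3 percent of the changed genes).

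Several lines differed more from WT as PGCLC than as EpiLC, and a test of that difference between the 2 stages singled these results out. The effect of the label Ovol2KO differed for 1112 genes (500 higher, 612 lower in PGCLC), that of TKO for 1357 (611 higher, 746 lower), that of Ovol2a-Tg for 434 (170 higher, 264 lower) and that of Ovol2b-Tg for 1096 (512 higher, 584 lower). The direction split depends on scaling: quantile scaling gave 534 higher and 540 lower in Ovol2KO, 681 and 664 in TKO, 231 and 228 in Ovol2a-Tg and 570 and 509 in Ovol2b-Tg, and limma-voom gave 311 and 669, 507 and 968, 163 and 452, and 389 and 794, in the same order. With the Ovol2b-Tg EpiLC pair averaged to 1 library its count was 947. Cdh1 was among the differing genes in all 4 lines, with log2 differences of −2.68 ± 0.13 in Ovol2KO (limma, BH adjusted p = 8.06e-17), −3.48 ± 0.13 in TKO (limma, BH adjusted p = 1.62e-20), −1.47 ± 0.13 in Ovol2a-Tg (limma, BH adjusted p = 2.02e-09) and −2.21 ± 0.13 in Ovol2b-Tg (limma, BH adjusted p = 1.93e-14). Ovol2 itself differed by −2.13 ± 0.39 in Ovol2KO (limma, BH adjusted p = 0.000132), −2.10 ± 0.39 in TKO (limma, BH adjusted p = 0.000114) and 1.93 ± 0.39 in Ovol2b-Tg (limma, BH adjusted p = 0.000464). Cldn4 (−4.17 ± 0.29), Epcam (−2.56 ± 0.16), Utf1 (−3.77 ± 0.27), Foxf1 (3.54 ± 0.32) and Hoxb6 (4.61 ± 0.42) also differed in Ovol2KO, named after their values were seen. The epithelial list had 21 falls and 1 rise in Ovol2KO (median −1.78, camera BH adjusted p = 1.07e-21), and the Hox list 21 rises (median 1.69, camera BH adjusted p = 1.65e-26), the same when adjusted over the list alone. In TKO the Hox list had 23 rises (median 2.47, camera BH adjusted p = 4.32e-27) and the naive list 12 falls (median −1.85, camera BH adjusted p = 9.39e-13), the same when adjusted over the list alone.

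Some transgenic PGCLC lay nearer to TKO than to WT: Ovol2b-Tg differed from TKO in 51 genes and from WT in 1197, and Cdh1-Tg in 331 and 1421, but Ovol2a-Tg in 475 and 494 and Ovol2a/2b-Tg in 1207 and 1099. Of 167 genes that set ESC of TKO apart from ESC of WT and Ovol2KO, the lowest share nearer to TKO in transgenic PGCLC was 49.1 percent, in Ovol2a/2b-Tg (95 percent interval 41.3 to 56.9), and Ovol2KO reached 62.3, so this test left a TKO background open. For the same genes in ESC the lowest share was 73.7 percent (66.3 to 80.2), against at most 30.5 in the other knockout-labelled lines, and the chromosome 16 medians of the transgenic PGCLC lay within 0.036 of TKO, as a TKO background predicts, though Ovol1KO also had a raised chromosome 16. Mid1 and Erdr1 were at 619 and 2660 TPM in TKO PGCLC but 7.56 and 3.94 in Ovol2b-Tg, near the 7.55 and 0.85 of Ovol2KO. In Ovol2a/2b-Tg they were at 33.9 and 122 TPM. Y-linked Eif2s3y was listed at 0 in Ovol2b-Tg and Ovol2KO PGCLC and stood at 0.149 TPM in Ovol2a/2b-Tg, against 0.85 in TKO. A loss of such genes within a line of TKO origin therefore cannot be told apart from another origin. Snrpn and Nnat in Ovol2b-Tg, at 117 and 0.463 TPM, lay nearer to TKO (93.6 and 3.69) than to Ovol2KO (0.179 and 46.1). The origin of the transgenic lines stays open. A batch that follows the naming styles would not set Ovol2b-Tg apart from WT, since it shares the style of WT and TKO. That rests on the labels alone. The 1197 and 51 genes define the pattern, so their ratio of 23.5 and their counts with 1 library left out only restate it and test no batch. Batches that the names do not mark, and those of the other 3 lines, stay open.

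Compared with TKO, Ovol2a/2b-Tg and Cdh1-Tg shared 17 genes changed the same way at all 3 stages, all lower and named after their values were seen: Fos, Egr1, Cyr61, Hist1h2aa, Hist2h2ab and Hist2h2ac, which are immediate early or histone genes, and Csl, Wdr89, BC048507, Acot10, Lamp3, Lrrc58, Aldoart1, G6pd2, Rpl37rt, Rasl2-9 and Cks1brt, which are neither. No other pair of transgenic lines shared more than 4, but none could have shared more than 6, since Ovol2a-Tg and Ovol2b-Tg had only 6 and 5 such genes against 48 in Ovol2a/2b-Tg and 22 in Cdh1-Tg, so a difference between library batches stays open. Cdh1 was raised over TKO in both lines, though in Ovol2a/2b-Tg PGCLC, at 174 TPM against 20.6 in TKO, it lay below the 316 of WT. Raised Cdh1 as the cause predicted that most of the 17 go the same way between WT and TKO, but only 17.6 percent did. WT and TKO also differ in many other genes, such as those on chromosome 16. The test therefore cannot set Cdh1 apart and leaves it open. Depth is argued against, on genes picked for being lower than TKO and therefore without the TKO libraries. In 6 other libraries of the same stage and depth range (5 EpiLC, 1 PGCLC, 0 ESC), 0 percent of 102 values were as low. The shares were 0.3 percent of 357 values in the 21 shallower libraries and 0.7 percent of 153 in the 9 deeper ones. Of these, 10 and 2 libraries were ESC. In a first test on Fos alone, however, 71.4 percent of 7 libraries of mixed stages were as low. The test of near-identical copies cannot decide, as its result fell between the bounds set for and against them. Of the genes, 25 percent had a copy (4 of 16, or 6 at 90 percent identity). That share lay above the 4.7 percent of all genes (Fisher exact p = 0.00562). At 90 percent identity the shares were 37.5 and 5.5 percent. Copies therefore stay open, matches under 90 percent identity were not counted, and no other biological explanation was tested.

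PGCLC labelled Ovol3KO held less mesoderm and more pluripotency expression, and over 100 genes specific to ESC the 10th percentile of the share of the ESC level was 0.3 percent (−0.5 to 1.6), and over 100 genes specific to EpiLC it was −1.1 percent (−7.1 to 1.2). The medians were 12.9 percent against 3.7 in Ovol1KO for ESC genes (90 of 100 higher) and 12.7 against 5.6 for EpiLC genes (85 of 100 higher). They run toward cells that stayed behind, while the 10th percentiles, whose intervals include 0, leave such cells open. Shares of this size are too small for the primitive streak list, where 25 of 31 genes fell (median log2 fold change −2.37). Cells that stayed behind are thus argued against as the whole cause of those falls, and a part stays open. A wrong line label is argued against by chromosome 8, whose median of 0.452 in PGCLC matched the ESC and EpiLC of the same label. In PGCLC of other lines it was at most 0.115, in Ovol1KO. The median was alike at every stage, so it cannot test a wrong stage label, which stays open. Chromosome 6 matched less well, at 0.186 in PGCLC against 0.345 and 0.343 in ESC and EpiLC but at most 0.025 in PGCLC of other lines, and only 40.5 percent of the genes shared by its ESC and EpiLC kept their direction (24.8 to 57.9). The higher dose of chromosomes 6 and 8 acting on their own genes is argued against as the whole cause, since they held 16.2 percent of the 625 higher genes (13.4 to 19.3) and 4 of the 19 higher pluripotency genes, but these shares exceed the 9.7 percent of all tested genes (Fisher exact p = 2.41e-07 for the 625; 7.3 percent of the lower genes), so a part in the rises stays open, and indirect effects of these chromosomes and an effect of the Ovol3 change were not tested apart.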

How the results depend on the processing

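The limma-voom fits, the averaged Ovol2b-Tg pair, the fits without chromosomes 6, 8 and 16 and the comparisons of the transgenic lines with TKO were chosen only after the result was seen. No called gene or list among those repeated turned its direction under any of 19634 alternative values for 1508 gene results and 414 list results. The list results are those of the PGCLC and WT stage comparisons. Lists of ESC and EpiLC against WT and of the differences between stages were not among them. A first version of the labels counted 289 sign changes as reversals, all in results past the threshold in neither setting (lowest adjusted p 0.119), and the rule was then changed so that they count as the same side.

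No count of changed genes moved by more than 1.5 times with no expression filter, quantile scaling, the averaged pair, chromosomes left out or fits of 2 stages. The 2 libraries of a group share only a number across lines, and a block for that number kept 36 of 36 counts. One fit of all 54 libraries gave 158 changed genes in PGCLC labelled Ovol1KO, 95 between Ovol2b-Tg and TKO PGCLC and 120 in ESC labelled Ovol1KO.

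A pseudocount of 0.1, which by construction widens the fold changes of scarce genes, gave 377 in EpiLC labelled Ovol2KO, 861 in Ovol3KO, 622 in TKO, 574 in Ovol2a-Tg, 495 in Ovol2b-Tg, 1258 in Ovol2a/2b-Tg and 1596 in Cdh1-Tg, and 409 in ESC labelled Ovol3KO. Limma-voom on recovered reads gave 19 in PGCLC labelled Ovol1KO, 866 in Ovol2a-Tg, 495 for Ovol2a-Tg against Ovol2b-Tg, and 751 and 1254 for Ovol2a/2b-Tg against Ovol2a-Tg and Ovol2b-Tg. Against TKO it gave 966 for Ovol2a-Tg, 97 for Ovol2b-Tg, 1855 for Ovol2a/2b-Tg and 747 for Cdh1-Tg. In EpiLC voom gave 310 in Ovol2KO, 923 in Ovol3KO, 622 in TKO, 730 in Ovol2a-Tg, 487 in Ovol2b-Tg, 1270 in Ovol2a/2b-Tg and 1681 in Cdh1-Tg. In ESC voom gave 45 in Ovol1KO, 925 in TKO, 1422 in Ovol2a-Tg, 999 in Ovol2a/2b-Tg and 1482 in Cdh1-Tg. Except for the pseudocount, the cause was not tested.

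Leaving out 1 library at a time, where the lone sample left in a group is assumed to vary like the other groups, moved 25 of 168 counts. PGCLC counts ranged from 13 to 489 in Ovol1KO, 290 to 607 in Ovol2a-Tg, 79 to 199 for TKO against Ovol2KO, 215 to 594 for Ovol2a-Tg against TKO, 11 to 109 for Ovol2b-Tg against TKO and 25 to 225 for Ovol2a-Tg against Ovol2b-Tg. EpiLC counts ranged from 38 to 161 in Ovol1KO, 159 to 344 in Ovol2KO, 335 to 696 in Ovol3KO, 242 to 516 in TKO, 256 to 481 in Ovol2a-Tg and 215 to 439 in Ovol2b-Tg. ESC counts ranged from 45 to 133 in Ovol1KO, and the Ovol2a-Tg difference between stages from 245 to 504. The cause was not tested. The steadier PGCLC counts ranged from 1064 to 1310 in Ovol2KO, 1645 to 2168 in Ovol3KO, 1468 to 1580 in TKO, 1116 to 1325 in Ovol2b-Tg, 1007 to 1215 in Ovol2a/2b-Tg and 1328 to 1565 in Cdh1-Tg.

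Single genes and lists lost their call most often when 1 library was left out (492 genes, 54 lists), with limma-voom (76 and 13), with the pseudocount of 0.1 (80 and 16) and, for lists, with an estimated correlation (168). The list counts cover the PGCLC and WT stage comparisons only. The libraries with the fewest reads, from 2.16 M, limit what can be said of scarce genes such as Ovol1.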

Other observations

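All tests in this part follow a plan except the choice of the genes named, which was made after their values were seen.

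EpiLC of the Ovol2a/2b-Tg line switched on genes of the early cleavage stage that WT EpiLC did not show. Zscan4f reached 44.6 ± 0.95 TPM and Zscan4c 33.2 ± 3.0 TPM, both listed at 0 in WT EpiLC. In the early cleavage-stage list 8 of 9 genes rose, the same when adjusted over the list alone (median 1.93, camera BH adjusted p = 8.72e-09). ESC of the same line had 5 rises, the same when adjusted over the list alone (median 1.34, camera BH adjusted p = 2.67e-09), and Zscan4f at 9.6 ± 4.3 TPM. In EpiLC 4 genes of the list rose in TKO (median 0.35, camera BH adjusted p = 0.00299), 4 in Ovol2a-Tg (median 0.84, camera BH adjusted p = 1.94e-05) and 4 in Ovol2b-Tg (median 0.45, camera BH adjusted p = 0.00109). These genes have near-identical copies, so which copy was read is uncertain.

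Neural genes were higher in EpiLC of several lines, with 5 rises in Cdh1-Tg (median 0.71, camera BH adjusted p = 0.00047) and 2 each in TKO (camera BH adjusted p = 0.000127) and Ovol2KO (camera BH adjusted p = 0.00107). ESC of Cdh1-Tg had 10 of 17 formative genes higher than WT ESC (median 1.04, camera BH adjusted p = 1.14e-08).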
